A study of Homo sapiens with 12 samples.

How the data were processed

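Gene expression was measured in MDA-MB-231, a human triple-negative breast cancer cell line, after transfection of small interfering RNAs (siRNAs). Cells received a control siRNA or 1 of 2 siRNA mixes against YAP (gene YAP1) and TAZ (gene WWTR1), at 33 nM on day 2. Medium was renewed on day 3 and RNA was collected on day 4, per the labels' protocols. Each of the 3 groups had 4 biological replicates with the letters A to D, handled in parallel per the series text, which gave 12 arrays. The siRNA sequences were not used here.

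RNA was hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays. The authors deposited 1 table of log2 expression values with 1 column per array, made with RMA per the submitters' processing notes; the software, its version and its options are not given in the sources used here. In its usual form RMA corrects background, gives the probes of all arrays 1 distribution and then summarises the probes of each probe set, so a shift of all genes in 1 direction would not be visible. After that summary the column medians still differed, from 5.69 to 5.78. The range and medians of the columns fit a log2 scale. The table held 54675 probe sets. GEO's platform annotation gave exactly 1 gene symbol to 41097 of them, several to 1801 and no gene here to 11777. Symbols were updated through gene IDs with the NCBI RefSeq gene table of GRCh38.p14 for 41043 probe sets, and 54 kept the older symbol. The reference table was used for names only, since the array files name no genome build, so no coordinates are given.

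Only probe sets with exactly 1 gene symbol were tested, without the 62 control probe sets. Of these 41091 probe sets, which named 19775 genes, 24650 had a mean over the 12 arrays above the 40th percentile (5.46 log2). The probe set with the highest mean stood for each gene, which left 13225 genes. Probe sets of 1 gene can differ in the transcripts they read, and those whose names end in _s_at or _x_at can bind transcripts of related genes.

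Differences were tested with limma (version 3.58.1, in R 4.3.3): lmFit with 3 group means on all 12 arrays, which left 9 residual degrees of freedom, and default eBayes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Errors of log2 differences are standard errors (SE) of this fit. Counts with a change of at least 2-fold were also made. There is no read depth on an array; the number of arrays limits the precision.

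A total of 22 gene lists was fixed, with the tests, the alternatives and the rule for named genes, before the data were examined. None of the lists was chosen on these samples. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison; camera compares a list with the other genes. Camera was repeated with the correlation estimated per list and on ranks, and fry was run as a test of whether the genes of a list move. Lists of markers of epithelial cells, leukocytes, endothelial cells and fibroblasts stood for other cells a culture could hold. Some list members had no probe set with a single gene name and were not analysed here.

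The named genes were YAP1, WWTR1, CCN1, CCN2, ANKRD1 and MYC, and the following. The 10 highest and the 10 lowest shared genes were ranked by the smaller of their 2 log2 changes, among genes past the threshold under both mixes whose 8 knockdown arrays all lay outside the control range. The 5 highest and 5 lowest genes of each mix against control, and the 8 highest and 8 lowest between the mixes, came from genes whose groups did not overlap. For each list, up to 2 members per direction that changed under both mixes were taken by the mean of their log2 changes. Together these were 117 genes; Y-linked genes were never named.

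Both mixes were compared with the same 4 control arrays. Chance similarity was therefore simulated 100 times with unchanged groups, and the controls were split into pairs in 6 assignments. Array level and RNA quality were tested with an exact two-sided permutation test, for which 4 arrays against 4 allow a smallest p of 0.0286. The replicate letters in the labels were checked for pairing by correlating deviations from the group means. Between mix 1 and control the correlations of same-letter arrays were 0.370, 0.251, 0.409 and 0.340 for A to D, all above 0.1. These letters were therefore treated as a possible pairing, which comes from these values and not from the labels. Replicate B did not correlate best with its own letter. Array medians also parted A and B from C and D, with 5.69 and 5.69 against 5.75 and 5.73 in control. With mix 1 they were 5.71 and 5.71 against 5.78 and 5.77. Mix 2 did not show this (5.73, 5.74, 5.74 and 5.73 for A to D). The correlations cannot tell pairing by letter from such a split of the arrays. The fit as fixed beforehand had no replicate block, and the blocked fit was an alternative.

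The alternatives were no filter and a filter at the 60th percentile, the mean of a gene's probe sets, no shared probe sets, each probe set as a feature of its own, another quantile normalization, centring on array medians, eBayes with trend and robust settings, array weights, fits of 2 groups only, a replicate block, each array left out in turn, an adjusted p of 0.01 and the other list tests. An alternative without mix 1 replicate B and mix 2 replicate D was added after the data had been seen. The gene and list tests were tested on simulated data with the means and spreads of these arrays for mix 1 versus control, over 13225 genes. Of 50 genes changed 1.25-fold, 48% were recovered; of those changed 1.5-fold, 90% were; and all 50 changed 2-fold and all 50 changed 4-fold were. Of 179 calls, 10 were of genes left unchanged. A simulated list that moved was found and an unmoved one was not (camera adjusted p of 1.25e-88 and 0.434). The simulated genes varied independently, so this did not test whether the preset correlation of 0.01 suits real lists. Only the genes named here were changed, against 8878 genes called with mix 1 in the data, so these rates may not carry over.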

Results

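The data were 12 arrays of RNA from MDA-MB-231 cells, 4 with control siRNA and 4 with each of 2 siRNA mixes against YAP and TAZ. YAP and TAZ are related transcriptional coactivators that are held in check by the Hippo kinase pathway and act mainly through the DNA-binding TEAD factors. The series asks how loss of both proteins changes gene expression in this line. After the filter, 13225 genes were compared, each with n = 4 arrays per group. Array medians lay between 5.69 and 5.78 log2, and replicate arrays of a group correlated across genes at 0.993 to 0.998.

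Both mixes lowered the mRNAs they target. YAP1 (its brightest probe set) had a level of 11.16 ± 0.10 log2 (SD, n = 4) with control siRNA, 8.15 ± 0.36 with mix 1 and 8.09 ± 0.10 with mix 2, so that 12.4% and 11.9% of the control level was left. WWTR1, which encodes TAZ, was at 11.40 ± 0.10 in control, 9.07 ± 0.22 with mix 1 and 8.95 ± 0.12 with mix 2, or 19.8% and 18.3% of control. The log2 changes were -3.01 (SE 0.13, limma adjusted p = 6.95e-11) and -3.07 (adjusted p = 4.56e-11) for YAP1, and -2.34 (SE 0.10, adjusted p = 3.6e-11) and -2.45 (adjusted p = 1.76e-11) for WWTR1. Between the mixes neither differed past the threshold, by -0.06 for YAP1 (adjusted p = 0.73) and -0.12 for WWTR1 (adjusted p = 0.344); without mix 1 replicate C the WWTR1 difference passed (-0.21, adjusted p = 0.0491). The other probe sets of both genes fell too. The least change was that of the dimmest WWTR1 probe set, with 33.2% left under mix 1 and 40.2% under mix 2, a difference of 0.28 log2 between the mixes (adjusted p = 0.044). Both other YAP1 probe sets were lower under mix 2 than under mix 1 (-0.48, adjusted p = 0.0268, and -0.20, adjusted p = 0.0129).

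**Figure D1:**
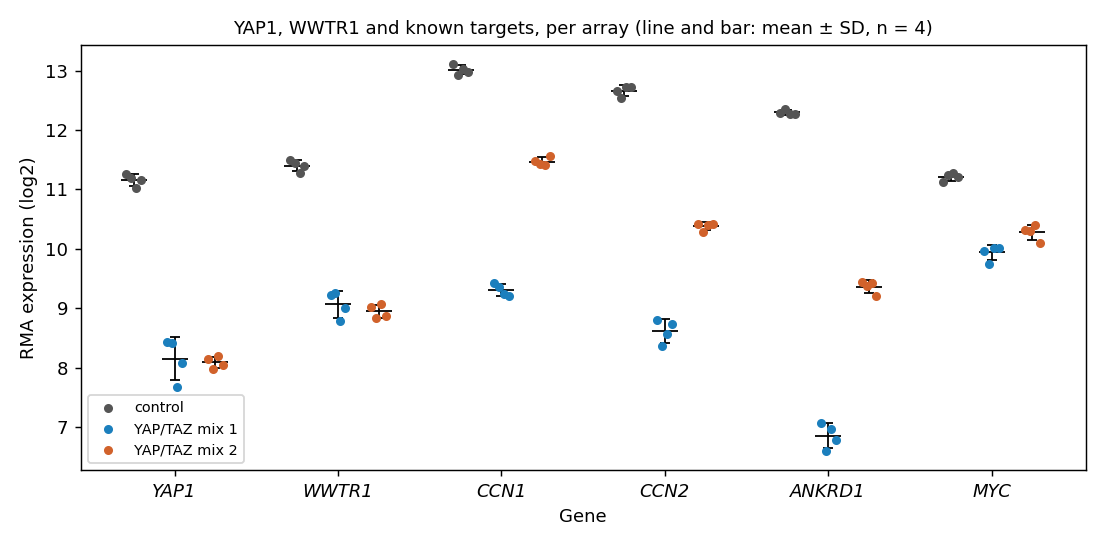
Expression (y axis, RMA log2) of 6 genes (x axis) on each array of the control, mix 1 and mix 2 groups; points are arrays, and lines with bars are the mean ± SD of n = 4. YAP1 lies near 11.16 in control and near 8.15 and 8.09 with the mixes, while CCN1, CCN2 and ANKRD1 lie lower with mix 1 (9.31, 8.62 and 6.86) than with mix 2 (11.47, 10.38 and 9.36).

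In cells with mix 1 against control, direct YAP/TAZ targets and genes of cell division fell, and genes of the interferon response, lysosomes and hypoxia rose. These list calls were made at the preset correlation and were lost with an estimated correlation (adjusted p = 0.0729 to 0.16). ANKRD1, a muscle-type ankyrin repeat protein and a standard YAP/TAZ target, fell from 12.30 ± 0.04 to 6.86 ± 0.21 log2 (SD, n = 4 each), 43.3-fold. CCN2 and CCN1, secreted matrix-associated proteins, fell 16.4-fold and 13.0-fold. The transcription factor gene MYC fell by 1.27 on the log2 scale (SE 0.08, adjusted p = 1.75e-09). Of 13225 genes, 4600 were higher and 4278 lower at an adjusted p below 0.05, of which 1070 and 1095 changed at least 2-fold. The 5 genes with the largest fitted falls were ANKRD1, the atypical cadherin gene FAT3 (-4.11), CCN2 (-4.04), CDCA7 (-3.80) and the secreted Wnt antagonist DKK1 (-3.74). CCN1 lay close to DKK1 (-3.71, SE 0.07), so the last place is not established. The 5 genes with the highest fitted rises were, in no established order, the urea transporter SLC14A1 (4.72), the proteoglycan SPOCK3 (4.54), the trefoil peptide TFF1 (4.42), the trypsinogen PRSS2 (4.35) and the junction protein CGNL1 (4.24). In control, SLC14A1 (3.13), SPOCK3 (4.97) and CGNL1 (5.16) lay below the filter value of 5.46 log2, near background, so the sizes of their rises are uncertain. The probe set of PRSS2 is of the kind that can also bind transcripts of related genes.

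Of 21 measured genes of the pan-cancer YAP/TAZ target list, 16 fell and 3 rose under mix 1, with a median of -0.77 log2 (camera adjusted p = 0.000146; adjusted p = 0.16 with an estimated correlation). The receptor tyrosine kinase AXL fell by 1.11 on the log2 scale, while RBMS3 (0.31), DOCK5 (0.24) and NT5E (0.70, chosen after its values were seen) rose; the rise of DOCK5 did not pass without shared probe sets (0.17, adjusted p = 0.0747). Among 22 genes of the Hippo pathway and the TEAD factors, 7 rose and 9 fell (median -0.02, adjusted p = 0.844). VGLL4, a cofactor that binds TEAD factors, rose (2.17), as did the kinase MAP4K4 (1.62). WWC1 and NF2, upstream parts of the pathway, fell (-1.41 and -0.94).

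Under mix 1, 43 of 44 genes of DNA replication and the G1/S transition fell, with a median of -1.99 (adjusted p = 5.36e-18; adjusted p = 0.0729 with an estimated correlation). Cyclin E2 (CCNE2) fell by 3.17 on the log2 scale (SE 0.13) and the log2 change of the replication factor CDC45 was -3.01 (SE 0.12). The 1 member that rose was E2F7 (0.78), chosen after its values were seen; it encodes a repressor among the E2F factors. All 35 genes of mitosis and G2/M fell (median -1.78, adjusted p = 1.33e-16; adjusted p = 0.102 with an estimated correlation), among them the mitotic kinesin KIF23 (-2.93) and the anaphase activator CDC20 (-2.31). All 25 genes of the MYC and ribosome biogenesis list fell as well (median -1.30, adjusted p = 2.18e-11; adjusted p = 0.0874 with an estimated correlation), such as the ribosome assembly factors RRS1 (-2.45) and NOP16 (-2.13). For NOP16, 2 other probe sets moved the other way. Of 17 cell cycle inhibitors and p53 targets, 12 rose and 5 fell (median 0.44, adjusted p = 0.0249; adjusted p = 0.282 with an estimated correlation). The stress cytokine GDF15 (3.20) and TP53INP1 (3.24) rose, and MDM2 (-0.44) and ZMAT3 (-1.18) fell. One of the other probe sets of TP53INP1 moved the other way, and MDM2 did not pass without shared probe sets (-0.07, adjusted p = 0.586).

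The interferon response list rose under mix 1, with 28 of 32 genes higher and 3 lower (median 1.32, adjusted p = 6.58e-09; adjusted p = 0.108 with an estimated correlation). IFI44L rose from 4.10 ± 0.13 to 6.82 ± 0.19 log2 and IFI27 from 6.47 ± 0.11 to 8.55 ± 0.10 (SD, n = 4), where the control level of IFI44L lay below the filter value, and IFIT5 fell by 0.66 on the log2 scale. OAS3 (-0.19) and HERC5 (-0.47), both chosen after their values were seen, were the others that fell. Of 25 genes of lysosomes and autophagy, 22 rose and 1 fell (median 0.90, adjusted p = 5.98e-07; adjusted p = 0.16 with an estimated correlation), among them the protease gene CTSD (2.13) and the autophagy gene WIPI1 (1.47). The 1 that fell was MCOLN1 (-0.24, adjusted p = 0.0434), which did not pass without control replicate A or B, mix 1 replicate A, C or D or mix 2 replicate A or B (adjusted p = 0.0531 to 0.145). Nor did MCOLN1 pass without a filter (adjusted p = 0.0659) or with only the 2 groups in the fit (adjusted p = 0.0655). The hypoxia response list had 16 of 19 genes higher and 1 lower (median 0.90, adjusted p = 0.00017; adjusted p = 0.0729 with an estimated correlation). NDRG1 rose by 3.59 on the log2 scale and MXI1, which encodes a MYC antagonist, by 1.62, while HILPDA fell (-0.96). The hypoxia list did not pass without shared probe sets (median 0.34, adjusted p = 0.0663). Of 27 AP-1 and immediate early genes 20 rose and 4 fell (median 0.71, adjusted p = 0.000821; adjusted p = 0.273 with an estimated correlation). The growth factor EREG (2.10) and the transcription factor KLF4 (1.43) rose, and the AP-1 subunit FOSL1 (-1.46) and MAFF (-0.88) fell, with DUSP1 (-0.48) and HBEGF (-0.74) chosen after their values were seen.

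Extracellular matrix and proteolysis genes rose under mix 1 in 22 of 31 cases and fell in 5 (median 0.73, adjusted p = 0.00144; adjusted p = 0.282 with an estimated correlation). The collagen gene COL6A1 (3.17) and the laminin gene LAMA4 (1.70) rose, and the vasoconstrictor peptide gene EDN1 (-1.89) and the protease gene PLAU (-0.91) fell. Another probe set of COL6A1 moved the other way under mix 2. Of 23 glycolysis and glucose uptake genes 15 rose and 3 fell (median 0.23, adjusted p = 0.0494), a call that was lost with an estimated correlation (adjusted p = 0.617), without shared probe sets (0.301), with centred arrays (0.0614), a filter at the 60th percentile (0.0706) or the mean of a gene's probe sets (0.0753) and without control replicates A (0.0512), C (0.0653) or D (0.0609), mix 1 replicates A (0.0519), B (0.0662) or C (0.0532), or mix 2 replicate C (0.0503). The glucose transporter SLC2A3 rose (3.16), and PFKFB2 (-1.33), for which another probe set moved the other way, LDHB (-0.42) and HK2 (-0.88, chosen after its values were seen) fell. The list of epithelial and luminal markers and that of leukocyte markers, which stood for other cells, rose too. The control cells already expressed some of the epithelial genes, such as KRT18 (12.88 log2), KRT19 (11.64) and EPCAM (9.57), while CDH1 (3.98) lay near background. Of 28 epithelial and luminal breast markers, 27 had a usable probe set and 19 passed the filter, which left out CDH1 and FOXA1 among others. Of these 19 genes 12 rose and 3 fell (median 0.51, adjusted p = 0.00329, or 0.244 with an estimated correlation), led by TFF1 and the secretory protein gene AGR2 (3.37). Those that fell were KRT7 (-0.66) and, chosen after their values were seen, EPCAM (-0.38) and GATA3 (-0.47). Of 11 leukocyte markers 6 rose and none fell (median 0.76, adjusted p = 0.0334; adjusted p = 0.129 with an estimated correlation), led by lysozyme (LYZ, 4.19) and HLA-DRA (1.93), an antigen-presenting molecule. Without the filter the leukocyte list did not pass (median 0.046, adjusted p = 0.0785).

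The remaining lists did not pass camera under mix 1. Their medians were -0.03 for 28 oxidative phosphorylation genes (4 higher, 11 lower, adjusted p = 0.379) and 0.23 for 18 cholesterol synthesis genes (10 higher, 5 lower, adjusted p = 0.379). The median was 0.005 for 34 actin and focal adhesion genes (11 higher, 13 lower, adjusted p = 0.592), where the mean and the test had the opposite sign, and 0.20 for 20 NF-kB and cytokine genes (10 higher, 5 lower, adjusted p = 0.379). For 30 genes of amino acid and endoplasmic reticulum stress it was -0.07 (14 higher, 10 lower, adjusted p = 0.772), with a mean and a test of the opposite sign. Mesenchymal breast cancer markers had a median of 0.22 (9 of 16 higher, 7 lower, adjusted p = 0.519), with fibronectin (FN1, 1.72) and S100A4 (1.67) higher and SNAI2 (-2.07) lower. Endothelial and fibroblast markers had a median of 0.07 (3 of 8 higher, 2 lower, adjusted p = 0.464), with COL1A1 (2.30) and PECAM1 (2.08) among those that rose; another probe set of COL1A1 moved the other way. The 19 reference genes had a median of 0.0075 (6 higher, 5 lower, adjusted p = 0.592), with a mean and a test of the opposite sign. Adjusted over the list alone, the counts of mix 1 were those given here, except 8 higher in the Hippo list, and 6 lower in the extracellular matrix list and in the NF-kB list.

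With mix 2 against control the same groups of division and growth genes fell, and the interferon list rose again, whereas the hypoxia and AP-1 lists did not pass. With an estimated correlation the mitosis (adjusted p = 0.0972), MYC and ribosome (adjusted p = 0.0972) and interferon (adjusted p = 0.122) calls were lost. ANKRD1 fell 7.63-fold to 9.36 ± 0.11 log2, CCN2 4.86-fold, CCN1 2.92-fold and MYC 1.91-fold (n = 4 per group). The 5 genes with the largest fitted falls were C4orf46 (-5.09), the ubiquitin ligase subunit SKP2 (-4.39), the RNA polymerase III subunit POLR3G (-4.39), the recombination protein RAD51AP1 (-4.33) and KIF23 (-4.32). Those with the highest fitted rises were SPINK4 (5.06), the antisense transcript VAC14-AS1 (4.94), the integrin ITGA10 (4.88), SPOCK3 (4.54) and the protease inhibitor CST1 (4.43). VAC14-AS1 (4.02), SPOCK3 (4.97) and CST1 (5.33) in control and C4orf46 (4.29) and POLR3G (5.13) with mix 2 lay below the filter value, so these sizes and their order are uncertain. Counts were 4848 higher and 4222 lower genes of 13225, with 1198 and 1236 at least 2-fold.

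The pan-cancer target list had 12 of 21 genes lower and 6 higher under mix 2 (median -0.56, adjusted p = 0.0285; adjusted p = 0.481 with an estimated correlation). This call was lost without shared probe sets (median -0.33, adjusted p = 0.11) and with a filter at the 60th percentile (adjusted p = 0.0573). All 44 genes of DNA replication and G1/S fell (median -2.35, adjusted p = 4.2e-21), a call that held with an estimated correlation (adjusted p = 0.0487), unlike that of the other lists. All 35 mitosis and G2/M genes fell (median -2.53, adjusted p = 5.07e-19; adjusted p = 0.0972 with an estimated correlation), and all 25 MYC and ribosome biogenesis genes (median -1.29, adjusted p = 7.46e-12; adjusted p = 0.0972 with an estimated correlation). Of the 32 interferon response genes 30 rose and 1 fell (median 1.23, adjusted p = 2.77e-09; adjusted p = 0.122 with an estimated correlation), with IFI27 at 2.73 and IFI44L at 1.68 log2 and IFIT5, the 1 that fell, at -0.98.

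Lysosome and autophagy genes rose under mix 2 in 19 of 25 cases and fell in 3 (median 0.58, adjusted p = 0.00131; adjusted p = 0.474 with an estimated correlation), with WIPI1 at 1.98 and CTSD at 1.20. MCOLN1 (-0.93) fell, as did LAMP2 (-1.18) and ATP6V1A (-0.96), chosen after their values were seen. Extracellular matrix genes rose in 19 of 31 cases and fell in 5 (median 0.53, adjusted p = 0.011; adjusted p = 0.481 with an estimated correlation), with COL6A1 at 2.50 and LAMA4 at 2.33. Epithelial and luminal markers rose in 14 of 19 cases and fell in 1, KRT7 (median 0.84, adjusted p = 0.000605; adjusted p = 0.202 with an estimated correlation). AGR2 rose from 9.13 ± 0.07 to 13.40 ± 0.05 log2 and TFF1 from 6.88 ± 0.18 to 11.04 ± 0.05 (SD, n = 4). KRT7 was at -0.50 and did not pass without shared probe sets under either mix (adjusted p = 0.72 and 0.269). The leukocyte list, with 7 of 11 genes higher and none lower, had a median of 0.53 that did not pass (adjusted p = 0.072); it passed without control replicate C (adjusted p = 0.0398) or mix 2 replicate A (adjusted p = 0.0498).

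For the other lists under mix 2, the median was 0.29 for hypoxia (11 of 19 higher, 5 lower, adjusted p = 0.332), 0.00 for AP-1 and immediate early genes (9 of 27 higher, 10 lower, adjusted p = 0.877), 0.09 for cell cycle inhibitors and p53 targets (8 of 17 higher, 6 lower, adjusted p = 0.61) and -0.04 for glycolysis (7 of 23 higher, 8 lower, adjusted p = 0.827). The Hippo and TEAD list had a median of -0.25 (6 of 22 higher, 11 lower, adjusted p = 0.288), and amino acid and endoplasmic reticulum stress -0.24 (13 of 30 higher, 15 lower, adjusted p = 0.62). Oxidative phosphorylation was at 0.07 (10 of 28 higher, 9 lower, adjusted p = 0.959), cholesterol synthesis at 0.11 (7 of 18 higher, 5 lower, adjusted p = 0.668) and actin and focal adhesion at 0.10 (16 of 34 higher, 11 lower, adjusted p = 0.827). NF-kB and cytokines were at 0.11 (7 of 20 higher, 7 lower, adjusted p = 0.877), mesenchymal markers at 0.12 (7 of 16 higher, 4 lower, adjusted p = 0.427), endothelial and fibroblast markers at 0.28 (4 of 8 higher, none lower, adjusted p = 0.275) and reference genes at 0.03 (7 of 19 higher, 7 lower, adjusted p = 0.877). The mean had the opposite sign for glycolysis, AP-1, oxidative phosphorylation and reference genes. Adjusted over the list alone, 16 stress genes were lower and 20 lysosome genes higher, and the other counts were as given.

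**Figure D2:**
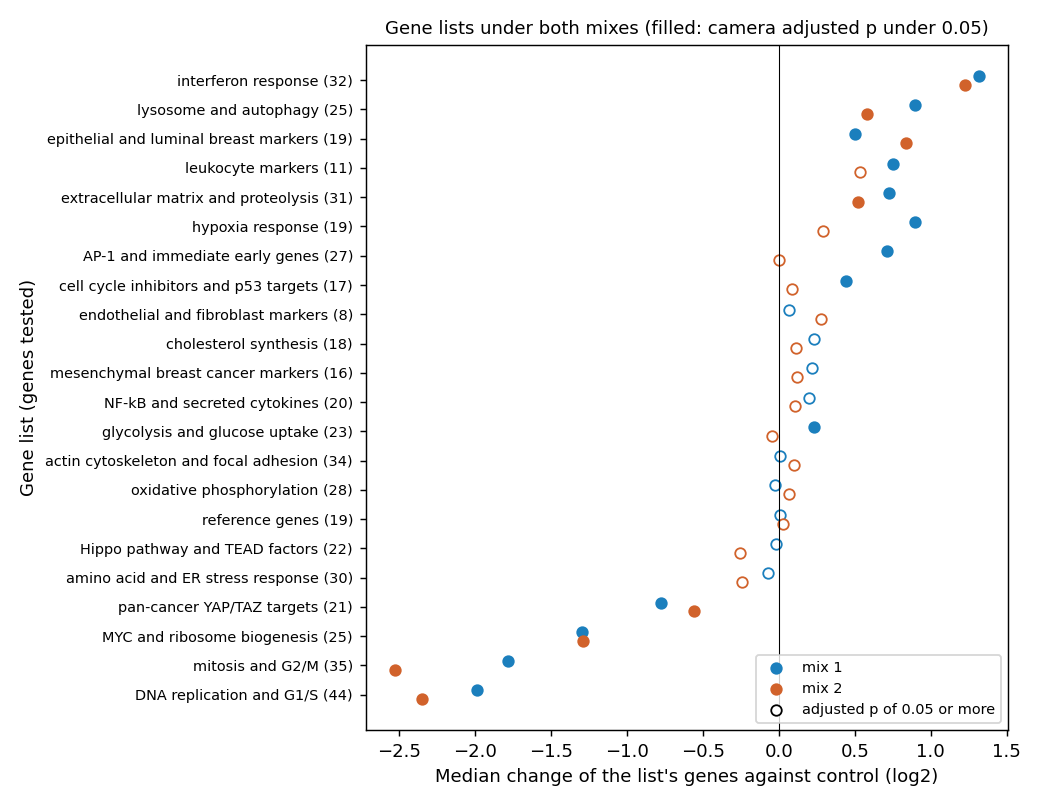
Median log2 change against control (x axis) of the genes of each list (y axis, number of genes tested in brackets) for mix 1 and mix 2; filled points have a camera adjusted p below 0.05 at the preset correlation and open points do not. The division and ribosome lists lie between -2.53 and -1.29 with both mixes and the interferon list at 1.32 and 1.23, while hypoxia lies at 0.90 with mix 1 and 0.29 with mix 2.

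Genes changed in the same direction by both mixes included the trefoil peptide genes TFF1 and TFF3, which rose, and CDC45 and CCNE2 of the DNA replication list, which fell. SPOCK3 rose from 4.97 ± 0.10 log2 to 9.51 ± 0.26 and 9.51 ± 0.33 (SD, n = 4). Also among the 10 highest were CGNL1 (4.24 with mix 1 and 4.42 with mix 2), PRSS2 (4.35 and 4.21), LYZ (4.19 and 4.22), TFF1 (4.42 and 4.15), CYP1B1 (4.12 and 4.01), a cytochrome P450, LTBP1 (3.97 and 3.83), which binds latent TGF-beta, ITGA10 (3.81 and 4.88), TFF3 (3.72 and 3.84) and CD96 (4.12 and 3.55). In control, SPOCK3, CGNL1, LYZ (4.96) and CD96 (5.46) lay at or below the filter value, so the sizes of their rises are uncertain. The 10 lowest held the nuclear lamin LMNB1 (-3.61 and -4.10), CDCA7 (-3.80 and -3.58), the replication factors GINS2 (-3.30 and -3.48) and CDC45 (-3.01 and -3.92), the recombination protein MND1 (-3.18 and -3.55), CCNE2 (-3.17 and -4.31), E2F8 (-3.44 and -3.15), the cytokine IL11 (-3.23 and -3.14), UHRF1 (-3.10 and -3.71), which maintains DNA methylation, and YAP1 itself. GINS2 did not pass under mix 2 without shared probe sets (-0.13, adjusted p = 0.219).

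Smaller shared changes stood in other lists. HMGCS1 (1.12 and 1.27) and SC5D (0.83 and 0.90) of cholesterol synthesis rose, and TMEM97 (-1.96 and -2.85) and ACAT2 (-1.11 and -0.89) fell. In the oxidative phosphorylation list NDUFA8 (0.41 and 0.63) rose and CYC1 (-0.89 and -1.09) fell; COX5B (0.24 and 0.25) lost its calls without shared probe sets (adjusted p = 0.576 under mix 2), and another probe set moved the other way under mix 1, and NDUFV1 (-0.59 and -0.49) did so under mix 2 with the mean of its probe sets (-0.14, adjusted p = 0.157), where its other probe set moved the other way. The integrin ITGB5 (1.96 and 1.90) rose, and the cytoskeletal genes DIAPH3 (-2.07 and -1.77) and MYH10 (-1.89 and -0.52) fell; TPM4 (1.11 and 0.88) did not pass under mix 2 with the mean of its probe sets (0.25, adjusted p = 0.159), and another of its probe sets moved the other way under mix 1. The cytokine gene CSF1 (3.11 and 2.53) and the signalling kinase gene IRAK2 (2.04 and 1.34) rose, and TNFAIP3 (-0.96 and -1.04), an inhibitor of NF-kB, fell. DDIT4 (1.72 and 1.45) and XBP1 (0.88 and 2.26) rose, and the mitochondrial one-carbon enzyme genes MTHFD2 (-1.82 and -1.50) and SHMT2 (-1.86 and -1.33) fell. Of the reference genes, B2M (0.67 and 0.48) and CHMP2A (0.65 and 1.22) rose and the transferrin receptor gene TFRC (-1.43 and -1.11) and IPO8 (-1.77 and -0.15) fell; another probe set of TFRC moved the other way under mix 1, and B2M did not pass under mix 2 without shared probe sets (0.26, adjusted p = 0.0618).

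In all, 3617 genes were higher and 3164 lower under both mixes, 725 and 730 of them at least 2-fold in both. Of these 6781 genes with a shared direction, 3851 also differed between the mixes past the threshold. A further 685 genes changed in opposite directions, 6 of these at least 2-fold in both. Independent lists of these sizes would share 1686 higher and 1366 lower genes, with 3037 opposite. Unchanged groups simulated against the shared controls gave 0.010 shared calls on average. With the controls split, 3197 to 3262 genes were shared higher and 2828 to 2907 lower. In 3231 of the shared higher genes and 2987 of the shared lower ones all 8 knockdown arrays lay outside the range of the 4 controls. Across genes, which are not independent replicates, the changes of the 2 mixes correlated at r = 0.815, against 0.50 in the simulation and 0.796 to 0.811 with split controls. Their covariance was 0.558, against 0.00444 simulated and 0.551 to 0.556 with split controls. The simulated r of 0.50 and the 0.010 shared calls follow from the setup, unchanged groups with shared controls. They do not give the overlap to be had by chance when many genes change.

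**Figure D3:**
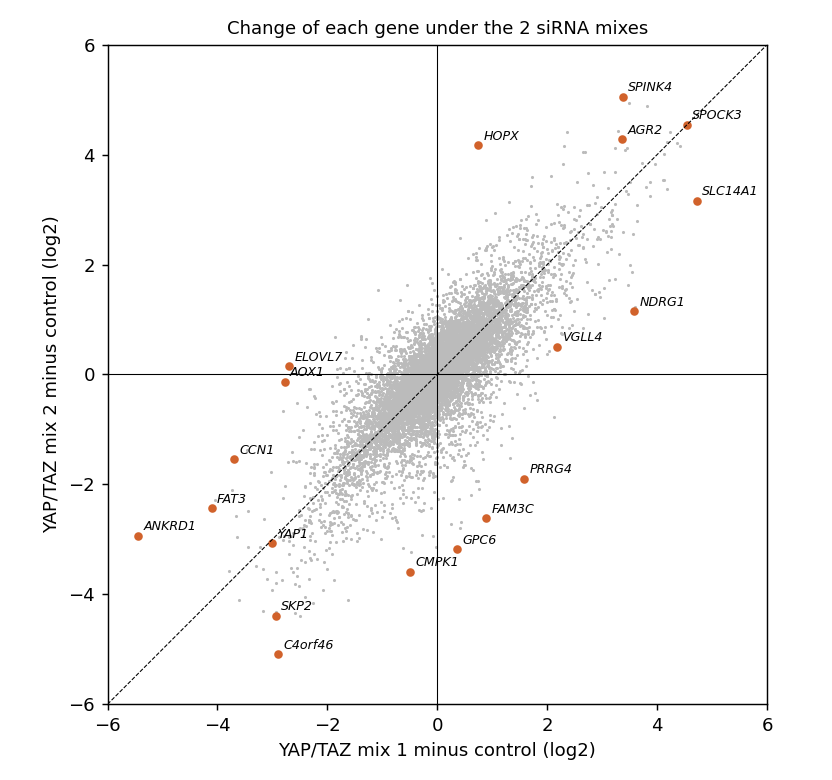
Each point is 1 of the 13225 genes, with its log2 change under mix 1 (x axis) and under mix 2 (y axis) against control; the dashed line marks equal changes and orange points are named genes. The changes of the 2 mixes correlate across genes (r = 0.815), while ANKRD1 (-5.44 and -2.93) and CCN1 (-3.71 and -1.55) lie to its upper left and GPC6 (0.36 and -3.18) and CMPK1 (-0.50 and -3.59) far below it.

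Between the 2 mixes, known YAP/TAZ targets were lower with mix 1, and mitotic, AP-1 and hypoxia genes were lower with mix 2. These list calls were lost with an estimated correlation (adjusted p = 0.128 to 0.351). ANKRD1 was 5.68-fold, CCN1 4.47-fold and CCN2 3.38-fold higher with mix 2 than with mix 1 (n = 4 each, adjusted p = 3.14e-11, 6.86e-12 and 6.81e-10). In total 3794 genes were higher and 3302 lower with mix 2, of which 348 and 478 differed at least 2-fold. The 8 genes furthest above mix 1 were HOPX (3.43), ELOVL7 (2.84), AOX1 (2.65), CEMIP (2.62), the pyruvate carrier MPC2 (2.53), ANKRD1 (2.51), the oxytocin receptor OXTR (2.28) and SP140 (2.18). HOPX was at 4.29 ± 0.19 log2 in control, 5.03 ± 0.06 with mix 1 and 8.46 ± 0.15 with mix 2 (SD, n = 4). The first 2 of these levels, and OXTR with mix 1 (4.73), lay below the filter value, so those sizes are uncertain. By contrast, the fatty acid elongase ELOVL7 and the aldehyde oxidase AOX1 fell with mix 1 (log2 changes of -2.69 and -2.78). With mix 2, AOX1 was at -0.13 (adjusted p = 0.0998), which passed with array weights (adjusted p = 0.0437) and with the mean of its probe sets (-0.21, adjusted p = 0.016). ELOVL7 was at 0.15 with mix 2 (adjusted p = 0.0474) and did not pass without any 1 control array, mix 1 replicate B or D or mix 2 replicate A, B or C (adjusted p = 0.0524 to 0.116), without a filter (0.083), without shared probe sets (0.0553), with centred arrays (0.122) or with trend and robust settings (0.0739).

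The 8 genes furthest below were the glypican GPC6 (-3.54), FAM3C (-3.50), PRRG4 (-3.49), TMTC3 (-3.20), OSTM1 (-3.13), the connexin GJA3 (-3.13), the nucleotide kinase CMPK1 (-3.10) and the site-2 protease MBTPS2 (-2.97). All 8 fell with mix 2, with log2 changes from -1.90 (PRRG4) to -3.59 (CMPK1); PRRG4 (4.70) and GJA3 (5.02) then lay below the filter value. With mix 1, 6 of them were higher than control, CMPK1 was lower (-0.50) and GJA3 was at -0.02 (adjusted p = 0.887). For OSTM1, 2 other probe sets moved the other way under mix 1, and with the mean of its probe sets that rise did not pass (0.055, adjusted p = 0.634).

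Among the lists, the pan-cancer targets were higher with mix 2 than with mix 1 (16 of 21 higher, 4 lower, median 0.65, adjusted p = 0.000797; adjusted p = 0.351 with an estimated correlation). Mitosis and G2/M genes were lower in 33 of 35 cases and higher in none (median -0.70, adjusted p = 2.24e-11; adjusted p = 0.299 with an estimated correlation). For DNA replication and G1/S, 25 of 44 were lower and 1, E2F8, was higher (median -0.26, adjusted p = 3.36e-06; adjusted p = 0.312 with an estimated correlation). AP-1 and immediate early genes were lower in 23 of 27 cases and higher in none (median -0.63, adjusted p = 1.52e-08; adjusted p = 0.212 with an estimated correlation), such as FOSL1 (-1.57). Hypoxia genes were lower in 14 of 19 cases and higher in 3 (median -0.67, adjusted p = 0.000196; adjusted p = 0.128 with an estimated correlation), with NDRG1 at -2.44. The higher call of E2F8 (0.29, adjusted p = 0.0421) did not pass without control replicate A or D, mix 1 replicate B or C or mix 2 replicate A, C or D (adjusted p = 0.0519 to 0.134). Nor did E2F8 pass with array weights (adjusted p = 0.0549), without a filter (0.0636) or with only the 2 groups in the fit (0.0719). The list of NF-kB and cytokines (11 of 20 lower, 2 higher, median -0.36, adjusted p = 0.0112; adjusted p = 0.396 with an estimated correlation), that of glycolysis (13 of 23 lower, 4 higher, median -0.29, adjusted p = 0.00543; adjusted p = 0.539 with an estimated correlation) and that of lysosomes (11 of 25 lower, 2 higher, median -0.14, adjusted p = 0.00894; adjusted p = 0.543 with an estimated correlation) were also lower. So were cell cycle inhibitors and p53 targets (12 of 17 lower, 5 higher, median -0.27, adjusted p = 0.0171; adjusted p = 0.396 with an estimated correlation) and the Hippo and TEAD list (11 of 22 lower, 5 higher, median -0.26, adjusted p = 0.033; adjusted p = 0.396 with an estimated correlation). Without shared probe sets the NF-kB (adjusted p = 0.0519), glycolysis (0.0763), lysosome (0.0596), p53 (0.211) and Hippo (0.261) lists did not pass; nor did the Hippo list with the mean of a gene's probe sets (adjusted p = 0.204).

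The other 12 lists did not differ past the threshold between the mixes, with adjusted p from 0.0904 for actin and focal adhesion (median 0.13) to 0.957 for endothelial and fibroblast markers (median 0.13). The medians were -0.07 for MYC and ribosome biogenesis (adjusted p = 0.555) and 0.09 for the interferon response (adjusted p = 0.618). Epithelial markers had a median of 0.08 (adjusted p = 0.446) and leukocyte markers of -0.01 (adjusted p = 0.784). For leukocyte markers and for endothelial and fibroblast markers the mean and the test had the opposite sign to the median. The actin list passed without a filter (adjusted p = 0.0464). Adjusted over the list alone, 15 glycolysis genes were lower, and 11 extracellular matrix and 8 stress genes were higher; the other counts were unchanged.

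Control probe sets for RNA quality and array level were compared last. The log2 difference between the 3′ and 5′ ends of ACTB was 1.70 ± 0.29 in control, 1.92 ± 0.28 with mix 1 and 1.53 ± 0.22 with mix 2 (SD, n = 4), and that of GAPDH was 0.39 ± 0.05, 0.43 ± 0.08 and 0.38 ± 0.04. The poly(A) spike-in probe sets averaged 9.30 ± 0.23 in control, 9.75 ± 0.60 with mix 1 and 9.26 ± 0.05 with mix 2. Of 18 exact two-sided permutation tests of 6 measures, the lowest p belonged to the hybridisation spike-ins, at 11.64 ± 0.04 with mix 2 and 11.56 ± 0.03 in control (exact permutation p = 0.0286, the smallest this design allows; adjusted p = 0.514). A single measure could not pass adjustment over 18 tests in this design, so these tests do not show that RNA quality was equal. They also ignored the letters. By letter A to D, the ACTB difference was 1.99, 1.88, 1.53 and 1.38 in control and higher each time with mix 1 (2.04, 2.24, 1.78 and 1.61). That of GAPDH was higher with mix 1 only for B and C. The first principal component, with 71.7% of the variance, parted both mixes from control, and the second, with 21.5%, parted the mixes from each other.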

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

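The tests of YAP1 and WWTR1 depletion, of a weaker effect of mix 2 on all genes and of unintended silencing by an siRNA mix, and the fit without 2 arrays, were chosen only after the result was seen.

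The pan-cancer YAP/TAZ targets differed between the mixes, with a median 0.65 log2 higher under mix 2 (adjusted p = 0.000797; adjusted p = 0.351 with an estimated correlation); 16 of 21 fell with mix 1 and 12 fell and 6 rose with mix 2, where the list call (adjusted p = 0.0285) was lost with an estimated correlation (adjusted p = 0.481), without shared probe sets (0.11) and with a filter at the 60th percentile (0.0573). A weaker depletion of the targeted mRNAs would leave YAP1 and WWTR1 higher under mix 2, but the mean of their 2 differences was -0.09 log2. A weaker effect of mix 2 on all genes is also argued against. Over 3152 other genes lower under both mixes, the median ratio of the mix 2 to the mix 1 change was 1.02 (quartiles 0.736 and 1.41), and over 12 list members it was 0.556 (0.498 and 0.912). Protein levels of YAP and TAZ were not analysed here, so a difference in protein depletion stays open, as does an effect of either mix on other mRNAs that may act on these targets.

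Genes that were at least 2-fold apart between the mixes numbered 826. If single faulty probe sets were the cause, the other probe sets of these genes would not follow. Over 460 genes with another probe set past the filter, the median of its difference divided by that of the brightest was 0.584 (quartiles 0.235 and 0.888). Of these ratios 89.8% were above 0, which argues against this for these 460 genes as a set. The lower quartile leaves it open for single genes, and the genes without another such probe set were not covered. Genes that moved at least 4-fold under 1 mix and by under 0.5 log2 under the other could reflect unintended silencing by an siRNA mix, which lowers mRNAs. Under mix 2, 24 of 25 such genes had fallen (96.0%, 95% exact interval 79.6 to 99.9), and under mix 1, 6 of 7 (85.7%, 42.1 to 99.6), against 53.4% and 43.8% of all genes that moved at least 4-fold under mix 2 and mix 1. Such silencing would be particular to each mix. Under mix 2 the falls outnumbered the rises as it would predict, while 7 genes are too few to tell under mix 1. The explanation stays open because the siRNA sequences were not used here. The intervals also treat genes of the same arrays as independent.

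Single markers such as TFF1 and LYZ rose under both mixes, which could come from other cells in the cultures; the epithelial list passed with both but not with an estimated correlation (adjusted p = 0.244 and 0.202), and the leukocyte list passed with mix 1 (adjusted p = 0.0334), not without a filter (0.0785) or with an estimated correlation (0.129), and did not pass with mix 2 (0.072). Luminal epithelial cells would bring EPCAM, CDH1, ESR1, GATA3 and FOXA1, whose median change was -0.05 (SD over the 5 genes 0.33) with mix 1 and 0.19 (SD 0.40) with mix 2. Other luminal markers were higher with both mixes, namely MUC1 (2.21 and 1.91), KRT19 (1.35 and 0.84), ERBB3 (1.17 and 1.27), CLDN7 (1.17 and 1.04) and SPDEF (0.99 and 1.34), all chosen after their values were seen. Leukocytes would bring PTPRC, CD14, TYROBP, FCER1G and CD74, whose median change was 0.11 (SD 0.78) with mix 1 and 0.43 (SD 0.73) with mix 2, with CD14 (1.12 and 1.24) and CD74 (1.56 and 1.55) higher and PTPRC (-0.24 and 0.43), TYROBP (0.02 and -0.19) and FCER1G (0.11 and 0.20) changing less. In control CD14 (5.15) lay below the filter value, so the size of its rise is uncertain. CDH1, FOXA1, PTPRC, TYROBP and FCER1G stayed below the filter value of 5.46 log2 in each group. They were thus not lifted off background by either mix, though small rises there can be missed. Above that value, EPCAM changed by -0.38 with mix 1 and 0.93 with mix 2, GATA3 by -0.47 and 0.065, and ESR1 by -0.05 and -0.125. Each median lay below 0.5 log2, the bound set beforehand for excluding a source. Only the luminal median with mix 1 did so by more than the SD of its genes. The rises of TFF1 and LYZ are the pattern to be explained, so they do not speak for either source. Both sources stay open, because the other medians did not clear the bound by the spread of their genes. No biological explanation was tested.

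Whether the counts of changed genes could arise from any grouping of the arrays was tested with other splits, fitted on the 2 groups alone. For mix 1 against control, 1 of the 35 splits, the real one, gave as many genes as its 8966, and the highest other split gave 1; of the 8 splits that part all 4 letter pairs, the others gave 0. For mix 2 against control (9178 genes) and mix 2 against mix 1 (6651 genes) it was again 1 of 35, with 0 genes in the highest other split. Of 100 groupings of the 12 arrays only 1, the real one, gave as many shared genes as the 6781 observed, and the highest other gave 0. The real arrangement thus gave the most genes each time, the best result that such a test allows. The other splits mix arrays of groups that differ, which widens the spread within them and pushes their counts toward 0. These splits therefore do not exclude chance.

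Other lists also differed between the mixes by their own test, as median log2 of mix 2 minus mix 1: Hippo pathway and TEAD factors -0.26, DNA replication and G1/S -0.26, mitosis and G2/M -0.70, cell cycle inhibitors and p53 targets -0.27, glycolysis and glucose uptake -0.29, NF-kB and cytokines -0.36, AP-1 and immediate early genes -0.63, hypoxia response -0.67, and lysosome and autophagy -0.14. None of these differences passed with an estimated correlation. Single genes called in opposite directions against control differed as well. ELOVL7 by 2.84, CEMIP by 2.62, MPC2 by 2.53, OXTR by 2.28 and SP140 by 2.18 were higher with mix 2. GPC6 (-3.54), FAM3C (-3.50), PRRG4 (-3.49), TMTC3 (-3.20), OSTM1 (-3.13) and MBTPS2 (-2.97) were lower. The opposite directions of ELOVL7 and OSTM1 depended on the processing. ELOVL7 was at 0.15 with mix 2, a call lost without any 1 control array (limma adjusted p = 0.0532 to 0.0971). The rise of OSTM1 with mix 1 did not pass with the mean of its probe sets (0.055, adjusted p = 0.634).

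Within groups of 4 arrays, 434 groups of values were searched for a single array far from the others by Dixon's test, and 30 had one; chance gives about 1 in 20. Mix 2 replicate D held 10 of them: CST1 at 9.59, MPC2 at 11.45, GDF15 at 9.06, COL6A1 at 9.87, DDIT4 at 11.88, CHMP2A at 11.63, ZMAT3 at 9.41, NDUFV1 at 9.59 and SNAI2 at 8.23 log2, and the p53 list score at -0.015. Control replicate B held 5, namely ANKRD1 at 12.36, ELOVL7 at 8.99, ACAT2 at 11.15, IPO8 at 10.47 and the reference gene score at 0.028, and mix 1 replicate C held 4, namely GDF15 at 9.98, HMGCS1 at 9.27, PLAU at 11.10 and the hypoxia score at 0.90. The rest were CCN2 at 10.28 (mix 2 B), FN1 at 12.64 (mix 2 C), CGNL1 at 4.98 and MPC2 at 10.77 (control C), HILPDA at 8.73 (control A), AXL at 13.16 (control D), MND1 at 7.19 and the stress list score at 0.058 (mix 1 A), ZMAT3 at 8.85 and RRS1 at 8.46 (mix 1 B) and FOSL1 at 8.53 (mix 1 D).

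Data outside the comparisons were of 2 kinds. Of 5228 probe sets without a single gene name that passed the filter, 1066 were higher and 934 lower under both mixes. That is a smaller share than the 3617 and 3164 of the 13225 tested genes. The poly(A) spike-in probe sets averaged 9.69, 10.56 and 9.66 log2 on mix 1 replicates A, B and C, above the highest control array at 9.52. Without mix 1 replicate B and mix 2 replicate D, an alternative chosen after seeing the data, 4608 genes were higher and 4345 lower with mix 1, 4966 and 4189 with mix 2, and 3967 and 2990 between the mixes.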

How the results depend on the processing

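Only the alternative without mix 1 replicate B and mix 2 replicate D was chosen after seeing the data. Against control, YAP1 and WWTR1 stayed past the threshold under each alternative, and with each array left out in turn YAP1 ranged from -3.10 to -2.85 (mix 1) and WWTR1 from -2.40 to -2.24. Of 379 pairs of a count and an alternative, 363 stayed within 1.5 times; the others came from testing each probe set as its own feature, which tests more features, and from 1 count at an adjusted p of 0.01. With each probe set as a feature, 8192 were higher and 7825 lower with mix 1 (1930 and 1831 at least 2-fold), 8374 and 7940 with mix 2 (1957 and 2209), 6349 and 6302 between the mixes (559 and 1011), and 6139 and 5710 were shared, with 1238 opposite. At an adjusted p of 0.01, 455 genes were opposite. The pan-cancer target list, with medians of -0.77, -0.56 and 0.65 for mix 1, mix 2 and their difference, no longer passed with an estimated correlation. Under mix 2 it was also lost with a filter at the 60th percentile (-0.56) and without shared probe sets (-0.33); the cause was not tested. The correlation of the mixes, 0.815, became 0.812 with array weights, 0.826 with the mean of a gene's probe sets, 0.810 without a filter, 0.811 after another quantile normalization, 0.796 without shared probe sets, 0.796 to 0.811 with split controls and 0.811 to 0.817 with 1 array left out. Between the mixes, the HMGCS1 difference changed sign with the mean of its probe sets (-0.016, limma adjusted p = 0.864), so its call was lost. That call was also lost without a filter (0.0931), with array weights (0.0949) and with only the 2 groups in the fit (0.0886). The same held without any 1 control array (0.0531 to 0.0627). WWC1 reversed without shared probe sets (0.65). The cause was not tested for either gene. Of 7956 pairs for named genes 7846 kept their side of the threshold and, where a value passed, their direction. Of the others 82 lost the call, 26 gained it and 2 changed sign. Of 1773 pairs for lists 1660 kept their side, 52 lost the call and 61 gained it. A change of sign was not counted where neither value passed, and for the other list tests only the side of the threshold was compared. Of the 52 list calls lost, 30 were lost with an estimated correlation, and of the 61 gained, 23 came from directional and 35 from mixed fry, which compares a list with no change and not with other genes. With the replicate block, 4762 genes were higher and 4432 lower with mix 1, where no named gene or list changed its call. Letters did not pair mix 2 with control (correlations 0.119, 0.0338, 0.0481 and 0.212 for A to D, not all best with their own letter) or with mix 1 (0.273, -0.0853, 0.202 and 0.191); the replicate block gave 5020 and 4360 genes with mix 2 and 4050 and 3520 between the mixes. Genes near the filter of 5.46 log2 lie close to background, where RMA understates changes.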

Other observations

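Gene families were tested beside the fixed lists, and some share members with them, such as MCM with 7 of 10. They were formed from the symbols after the data had been seen, as sets of at least 10 tested genes with the same symbol stem, 145 in all, and 16 families were lower and 3 higher under both mixes in camera at the preset correlation. None of these calls held with an estimated correlation, and the directions given here were the same after another quantile normalization and after centring each array on its median. Of 22 nucleoporin genes (NUP), which build the nuclear pore, 21 fell with mix 1, and 19 fell and 1 rose with mix 2 (medians -0.88 and -0.91 log2, adjusted p = 1.21e-07 and 2.46e-06; adjusted p = 0.402 and 0.461 with an estimated correlation). All 10 genes of the RNA exosome (EXOSC), which degrades and trims RNA, fell with both mixes (medians -1.30 and -1.40, adjusted p = 0.000146 and 0.000167; adjusted p = 0.543 and 0.536 with an estimated correlation). Genes for proteins of the large mitochondrial ribosome subunit (MRPL) fell in 43 and 38 of 48 cases (medians -0.55 and -0.51, adjusted p = 6.69e-08 and 1.15e-05; adjusted p = 0.68 and 0.656 with an estimated correlation), and 2 rose with each mix.

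Of the 3 families that were higher, 1 (ST) mixes sialyltransferases with unrelated genes; 11 of its 16 genes rose with mix 1 and 12 with mix 2, and 1 fell with each (medians 0.33 and 0.42, adjusted p = 0.0219 and 0.0308; adjusted p = 0.543 and 0.55 with an estimated correlation). Of 18 genes of intraflagellar transport (IFT), which carries cargo along cilia, 15 rose with mix 1 and 16 with mix 2, and 1 fell with each (medians 0.61 and 0.91, adjusted p = 0.00308 and 0.0003; adjusted p = 0.543 and 0.461 with an estimated correlation). Of 16 HLA genes, 1 of them also in the leukocyte list, which include antigen-presenting molecules and pseudogenes, 13 and 14 rose and none fell (medians 1.08 and 0.97, adjusted p = 8.39e-05 and 0.000167; adjusted p = 0.402 and 0.461 with an estimated correlation). HLA genes resemble each other closely, so their probe sets can bind each other's transcripts, and which members rose is uncertain.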
